A study of Homo sapiens with 108 samples.

How the data were processed

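Each sample was RNA of 1 melanoma line and condition, extracted with ISOGEN and then RNeasy, labelled with biotin and hybridised to a single-colour CodeLink whole human genome array, per the labels' protocols. The deposited table gives each array's values as spot intensity on a linear scale. With missing values counted as low, between 50.0% and 51.8% of the probes of each array lay below 1, as for intensity relative to the array's own median spot. The software and further steps behind this scaling are not given in the sources used here. The medians of the measured values ran from 1.02 to 1.32 over the arrays. Missing values numbered 1000 to 8034 per array and were more frequent among dim probes, at 41.3% of values in the dimmest 10% of the probes and 0.476% in the brightest 10%. No column was left unassigned, and no pair of arrays held identical values. Replicate arrays of a group correlated with r = 0.987 to 0.998 across probes.

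Samples were grouped by the line, beam, dose and time in the labels. The comparisons, main tests, gene lists, rule for named genes and most alternatives were set before the data were examined. Values were transformed to log2. A rule set in advance chose quantile normalization between arrays when the array medians ranged over more than 0.1 on the log2 scale, and they ranged over 0.38, so quantile normalization was applied, with median centring as an alternative. Probes were kept when at most 10% of the values were missing, which held for 44606 of 54359 probes, when the mean log2 value lay above the 40th percentile (-0.41), and when every group had a value, which left 32060. Of all probes, 178 had no value on any array. Fits within a line used the 28795 to 30014 kept probes with all values in that line.

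The annotation given with the arrays listed 24377 probes, 23472 with 1 gene symbol and 905 with several, and 29982 probes were unnamed here. Of those with 1 symbol, 23434 matched the RefSeq gene table (assembly GRCh38.p14) by Entrez identifier, and 0 symbols needed an update. No gene was named from a probe with several symbols. Among kept probes, 16723 had 1 symbol, for 13662 genes. A gene is represented by its kept probe with the highest mean, a choice that matters for the 2580 genes with several. Among called genes with other kept probes, another probe had the opposite sign in 158 of 359 at 3 h after carbon ions (21 of them called), 91 of 214 at 1 h after carbon ions (13 called), 60 of 130 at 3 h after X-rays (4 called) and 12 of 23 at 1 h after X-rays (1 called). A level that was planned is not reported here. Coordinates are not printed.

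Comparisons across lines used 1 value per line and probe, the mean log2 of the irradiated arrays minus that of the unirradiated arrays of the same line and beam, in limma (version 3.58.1, R 4.3.3; lmFit and eBayes with a trend) with an intercept over 6 lines, Benjamini-Hochberg adjustment at 0.05 over all kept probes, and tests on both sides. The same fit served the difference between beams at each time, the difference between 3 h and 1 h averaged over beams, and the unirradiated controls of both beams. Within each line, limma's moderated F over the 4 contrasts was used on the 18 arrays.

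The 17 gene lists held 285 genes, 222 of them measured: p53 targets, immediate early genes, NF-kB targets, genes of G2 phase and mitosis, genes of the G1/S transition, histones, DNA repair genes, melanocyte genes, apoptosis genes, interferon-stimulated genes, heat shock genes, integrated stress response genes, NRF2 targets, ribosomal proteins, and markers of fibroblasts, keratinocytes and leukocytes as other cell types. Each was tested with limma's cameraPR with a preset correlation of 0.01, adjusted over the 17 lists and 4 contrasts. With an estimated correlation no list passed in any contrast. The lists were also tested on the differences between beams and between times, as a family of their own added after the data were seen. An exact sign-flip test over the 6 lines, whose smallest p is 0.03125, stands beside some list values. The difference between lines was tested by the F of line by irradiation on a score per array, against 10000 permutations of residuals, for both leading lists and for CDKN1A, MDM2 and GDF15. Of these, only the test of the p53 targets was among those set in advance. Added after the data were seen, each line's mean change at 3 h was taken as 1 value per beam, and the F of line over line by beam was set against all 720 orders of the lines of 1 beam, which assumes that the sets of the beams shared no culture. Also added then, the distance of CDKN1A, MDM2 and GDF15 to the highest spot of each array was taken from the deposited values, and tests between lines were repeated without targets or lines within 1 log2 of it.

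The text names, for each comparison, genes among up to 10 with the largest rise and 10 with the largest fall that passed and moved the same way in all 6 lines (or, with fewer than 3, the 3 with the smallest p, said not to pass), CDKN1A, MDM2 and GDF15 throughout, up to 4 members per list with the largest mean change, and up to 3 rises and 3 falls per line at 3 h.

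The fits across lines and within lines were tested on simulated data drawn for the 32060 probes, with changes planted at 3 h after both beams and none at 1 h or between beams. Normalization, the list tests and the exact test over beam sets were not simulated. With 100 probes changed by 0.5 and 100 by 1 on the log2 scale, the comparison of 3 h after carbon ions recovered 100% and 100%, and that of X-rays 99% and 100%. This was without a spread shared by the arrays of a group. With a shared spread of 0.1 log2, recovery was 97% and 100% after carbon ions and 100% and 100% after X-rays. Each planted change was equal in all 6 lines, so recovery of a response that differs between lines was not tested. The F within lines recovered 77% to 86% at 0.5 and 99% to 100% at 1, with 6 to 16 unchanged probes called when the arrays of a group shared no spread. Alternatives were median centring, no filter on level, an offset of 0.578 (the 25th percentile) before log2, leaving out each replicate number or each line, a replicate block, a fit on all arrays with and without such a block (with missing values its blocked standard errors are approximate), and camera with an estimated correlation. Chosen after the data were seen were a correction for array brightness (the slope of each probe on the log2 highest value of the array, taken within groups), the values as deposited, and leaving out the carbon-ion 1 h array 2 of MeWo, which had the most missing values, or the unirradiated carbon-ion array 1 of Colo679, which correlated least with its group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.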

Results

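Gene expression was measured in 6 human melanoma cell lines (C32TG, MeWo, Colo679, HMV-II, 92-1 and HMV-I) after 2 Gy of carbon ions or of X-rays. RNA was collected 1 h and 3 h after irradiation, and each line had its own unirradiated cells for each beam, so that the beams shared no controls while the 1 h and 3 h samples of a beam did. Each of the 36 combinations of line, beam and condition was measured on 3 single-colour arrays, 18 for each line. Carbon ions deposit their energy along dense tracks, X-rays more evenly. The arrays carried 54359 probes, of which 32060 were kept for testing. The number of arrays limits the precision, and since the labels do not say whether the 3 arrays of a group came from separate cultures, p-values within a line cover only the spread between these arrays. Across lines, each line gave 1 value per comparison (irradiated minus unirradiated, log2), and changes are given as the mean ± SD over 6 lines with limma's adjusted p.

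At 3 h after carbon ions, genes of the p53 response rose and genes of mitosis fell. CDKN1A (probe 156110), the p21 inhibitor of cyclin-dependent kinases, rose by 1.20 ± 0.74 (SD, n = 6 lines; adjusted p = 0.00644), a 2.29-fold increase seen in 6 of 6 lines. In C32TG, Colo679 and HMV-II its 3 h values lay within 0.76 log2 of the highest spot of the array, which leaves little room for a larger rise. SESN2 and SESN1, stress-induced regulators of growth signalling, rose by 1.07 ± 0.59 (adjusted p = 0.00439) and 1.06 ± 0.81 (adjusted p = 0.0148), and TP53INP1, a p53-induced nuclear protein, by 0.92 ± 0.60 (adjusted p = 0.00839), each in 6 of 6 lines. FAS, the death receptor, rose by 0.87 ± 0.62 (adjusted p = 0.0125) and the stress transcription factor ATF3 by 0.92 ± 0.53 (adjusted p = 0.00532). Of 26 measured p53 targets, 15 rose and 0 fell among all genes tested (18 rose and 1 fell when adjusted over the list alone). Their median change was 0.49 and the list test gave an adjusted p of 2.27e-08, with adjusted p = 0.424 with an estimated correlation.

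The largest falls at 3 h after carbon ions included NEAT1, a nuclear long non-coding RNA that builds paraspeckles, which fell by 1.28 on the log2 scale (SD 0.59; adjusted p = 0.00205), and the DNA helicase PIF1 (probe 140040), which fell by 1.15 (SD 0.19; adjusted p = 6.37e-05), each in 6 of 6 lines. A second probe of each gene also fell, by 0.74 for NEAT1 and by 0.71 for PIF1. Of 25 measured genes of G2 phase and mitosis, 19 fell (23 when adjusted over the list alone) and 0 rose, with a median of -0.32 (-0.21 with median centring, adjusted p = 2.69e-12) and a lower list mean in 6 of 6 lines. The mitotic kinesin KIF20A fell by 0.72 (SD 0.36; adjusted p = 0.00368), the centromeric histone CENPA by 0.67 (SD 0.19; adjusted p = 9.86e-04), the spindle checkpoint kinase BUB1B by 0.64 (SD 0.42; adjusted p = 0.00987) and the spindle protein ASPM by 0.59 (SD 0.31; adjusted p = 0.00485). The list test gave an adjusted p of 3.87e-17, and adjusted p = 0.419 with an estimated correlation. KLF10, a transcription factor induced by TGF-beta, fell by 0.74 (SD 0.31; adjusted p = 0.00203), and UBE2V2, a ubiquitin-conjugating enzyme variant, by 0.81 (SD 0.39; adjusted p = 0.00304).

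In total 4300 of 32060 probes were called at 3 h after carbon ions, 2063 higher and 2237 lower, for 994 named genes that rose and 622 that fell. Most changes were small, with a median absolute change of 0.26 among called probes, 131 probes beyond 1.5-fold and 7 beyond 2-fold. The balance of rises and falls depended on the scaling between arrays: 48.0% of calls were rises with quantile normalization, 76.5% of 7089 calls with median centring and 38.0% with the values as deposited. The number of calls also depended on single lines, being 1813 without 92-1, 2009 without HMV-II, 2016 without Colo679, 2277 without HMV-I and 2221 without the arrays numbered 1.

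At 1 h after carbon ions, ATF3 rose by 0.66 ± 0.28 (adjusted p = 8.39e-04), NFKBIA, the inhibitor of NF-kB that is itself an NF-kB target, by 0.58 ± 0.19 (adjusted p = 3.44e-04), and GADD45A, a DNA damage-inducible stress sensor, by 0.56 ± 0.32 (adjusted p = 0.00371), each in 6 of 6 lines. The polo-like kinase PLK2 rose by 0.43 ± 0.24 (adjusted p = 0.00391), the interferon regulatory factor IRF1 by 0.43 ± 0.14 (adjusted p = 8.32e-04), and CDKN1A by 0.29 ± 0.13 (adjusted p = 0.00383), while a second IRF1 probe stood at 0.15 (adjusted p = 0.0922). NEAT1 fell by 0.81 (SD 0.51; adjusted p = 0.00508), and CLK1, a kinase of splicing factors, by 0.55 (SD 0.20; adjusted p = 5.40e-04). Of the p53 targets, 7 of 26 rose (8 when adjusted over the list alone), with a median of 0.11 and an adjusted p of 1.46e-04, and adjusted p = 0.419 with an estimated correlation. Of the 25 mitotic genes only CENPA fell, by 0.23 (SD 0.12; adjusted p = 0.0123), a call lost with the values as deposited (0.0567). The count was 1 as well when adjusted over the list alone, and the list did not pass the test (median -0.037, adjusted p = 0.250).

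Calls at 1 h after carbon ions numbered 3430, 1497 higher and 1933 lower, with a median absolute change of 0.24, and covered 611 named genes that rose and 379 that fell. Rises were 43.6% of calls with quantile normalization, 66.9% of 5235 calls with median centring and 50.8% with the values as deposited. Leaving out Colo679, 92-1, HMV-I or MeWo left 1904, 2136, 2251 and 2279 calls, and leaving out the arrays numbered 1 or 2 left 2102 and 2172.

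At 1 h after X-rays, NFKBIA rose by 0.69 ± 0.19 (adjusted p = 9.76e-04) and GADD45B, a stress-induced regulator of MAP kinase signalling, by 0.63 ± 0.11 (adjusted p = 1.52e-04), each in 6 of 6 lines, although a second GADD45B probe stood at -0.080 (adjusted p = 0.561). IRF1 rose by 0.35 ± 0.10 (adjusted p = 0.00595; second probe 0.095, adjusted p = 0.450), and the non-coding host transcript MIR181A2HG by 0.54 ± 0.16 (adjusted p = 0.00172). CLK4, a kinase of splicing factors, fell by 0.49 (SD 0.22; adjusted p = 0.00656). ATF3 rose by 0.49 ± 0.33 (adjusted p = 0.0330), a call lost without C32TG, Colo679 or HMV-II, where its adjusted p reached 0.0883, and without the arrays numbered 3 (0.0762). CDKN1A stood at 0.26 ± 0.19, higher in 6 of 6 lines, and did not pass (adjusted p = 0.0539). Of the p53 targets, 2 of 26 rose (4 when adjusted over the list alone), namely PLK2 by 0.42 ± 0.23 (adjusted p = 0.0159) and GADD45A by 0.47 ± 0.33 (adjusted p = 0.0351). PLK2 lost its call without HMV-I (0.0576) or the arrays numbered 3 (0.0556). GADD45A, higher in 5 of 6 lines, lost it without any of 5 lines, all but HMV-I, and without the arrays numbered 2 or 3, with an adjusted p of up to 0.103. The p53 list median was 0.070 with an adjusted p of 0.00124, and adjusted p = 0.419 with an estimated correlation. It was 0.025 without the arrays numbered 1 (adjusted p = 0.0312). Without 92-1 or HMV-II it was 0.043 (adjusted p = 0.0253 and 0.0261). Mitotic genes did not pass (median 0.013, adjusted p = 0.989), with 0 of 25 called by limma among all genes tested, when adjusted over the list alone, or at an unadjusted p under 0.05.

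Probes called at 1 h after X-rays numbered 370, with 118 higher and 252 lower, covering 37 named genes that rose and 56 that fell. Rises made up 31.9% of these, against 47.5% of 278 calls with median centring. This count was the least stable of the irradiation counts: it was 113 without Colo679, 114 without C32TG, 135 without HMV-II, 146 without 92-1 and 153 without HMV-I, 134 to 168 when the arrays of any 1 replicate number were left out, 239 without the filter on level and 217 after correction for array brightness.

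At 3 h after X-rays, p53 targets rose and some mitotic genes fell, as after carbon ions. CDKN1A rose by 1.18 ± 0.81 (adjusted p = 0.00707), SESN1 by 0.93 ± 0.58 (adjusted p = 0.00503), TP53INP1 by 0.85 ± 0.58 (adjusted p = 0.00778), FAS by 0.83 ± 0.45 (adjusted p = 0.00309) and ATF3 by 0.88 ± 0.48 (adjusted p = 0.00320), each in 6 of 6 lines. ACER2, an alkaline ceramidase, rose by 0.77 ± 0.55 (adjusted p = 0.00938) and the polo-like kinase PLK3 by 0.80 ± 0.53 (adjusted p = 0.00726). Of the 26 p53 targets, 13 rose (21 when adjusted over the list alone) and 0 fell. Their median was 0.48 with an adjusted p of 2.35e-15, and adjusted p = 0.419 with an estimated correlation. NEAT1 fell by 0.88 (SD 0.39; adjusted p = 0.00212), with a second probe at -0.18 (adjusted p = 0.10), and PIF1 by 0.66 (SD 0.39; adjusted p = 0.00508), with a second probe at -0.33 (adjusted p = 0.0835). ID1, an inhibitor of differentiation factors, fell by 0.61 (SD 0.37; adjusted p = 0.00597), and the kinetochore protein SPDL1 by 0.61 (SD 0.42; adjusted p = 0.00999).

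Of the 25 mitotic genes, 4 fell at 3 h after X-rays (6 when adjusted over the list alone), among them ASPM, by 0.28 (SD 0.12; adjusted p = 0.00904). The list median was -0.14 (-0.082 with median centring, adjusted p = 4.95e-04), its mean was lower in 5 of 6 lines, and the adjusted p was 7.97e-05, with adjusted p = 0.419 with an estimated correlation. X-rays at 3 h gave 2292 called probes, 950 higher and 1342 lower, for 348 named genes that rose and 245 that fell. Rises were 41.4% of calls with quantile normalization, 70.4% of 3670 calls with median centring and 24.5% with the values as deposited. The count fell to 1159 without 92-1, 1171 without MeWo, 1298 without HMV-II and 1360 without the arrays numbered 1.

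Set against each other, the beams moved many of the same probes in the same direction. Across the 32060 probes, which are not independent replicates, the mean changes of both beams correlated with r = 0.712 at 1 h (Spearman 0.628) and r = 0.805 at 3 h (Spearman 0.762), with separate controls for each beam. At 3 h, 546 probes rose after both beams against 61.1 for independent lists, 1028 fell after both against 93.6, and 0 were called in opposite directions. At 1 h the shared calls were 90 rises against 5.51 and 217 falls against 15.2. Within single lines the correlation was lower, 0.259 to 0.471 at 1 h and 0.332 to 0.513 at 3 h.

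No single probe passed the direct test of carbon ions against X-rays. Limma called 0 probes at 1 h and 0 at 3 h, where 2421 and 1430 had an unadjusted p under 0.05, while a fit on all arrays, which leaves out the spread between lines, called 292 and 368 (441 and 504 with a replicate block). The median 95% interval of a probe reached 0.14 on either side of the estimate at 1 h and 0.17 at 3 h. For CDKN1A the beam difference at 3 h was 0.018 ± 0.24 (adjusted p = 1.00, higher in 3 of 6 lines), with 3 lines near the top of the scale, and for the p53 list the mean difference was 0.029 ± 0.078 over 6 lines (95% interval -0.053 to 0.11; exact sign-flip p = 0.406). CENPA was among the 3 lower genes of smallest p at 3 h and its change from its own controls was lower after carbon ions in 6 of 6 lines (-0.44 ± 0.24), but did not pass (adjusted p = 0.932). At 1 h the change of GPX1, a glutathione peroxidase, was 0.23 ± 0.13 higher after carbon ions in 6 of 6 lines without passing (adjusted p = 0.437).

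As a list, the mitotic genes fell further from their own unirradiated controls after carbon ions than after X-rays at 3 h. The median difference between the changes was -0.22, with 10 of 25 genes changing further downward when adjusted over the list alone, 16 at an unadjusted p under 0.05 and 0 among all genes tested by limma. The difference of the list mean was negative in 5 of 6 lines, Colo679 being the exception. The list test gave an adjusted p of 1.02e-21, with adjusted p = 0.227 with an estimated correlation, and the exact sign-flip test over lines gave p = 0.0625. The unirradiated cells differed too: before irradiation the list mean was 0.31 ± 0.40 higher in the carbon-ion controls than in the X-ray controls, and higher in 4 of 6 lines (exact sign-flip p = 0.188). The irradiated arrays by themselves did not show lower mitotic genes after carbon ions at 3 h. Their list mean was 0.10 ± 0.30 above that after X-rays and higher in 3 of 6 lines (exact sign-flip p = 0.469). Over all probes, the unirradiated controls of the beams gave 0 calls across lines in limma, with 3116 at an unadjusted p under 0.05 and 17716 called in the fit on all arrays (14822 with a replicate block). The smallest p among the higher genes belonged to SCD, the stearoyl-CoA desaturase, which was 0.97 ± 0.43 higher in the carbon-ion controls in 6 of 6 lines and did not pass (adjusted p = 0.387).

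Between 1 h and 3 h, averaged over both beams, p53 targets rose further and mitotic genes fell further. This comparison used irradiated arrays only, and the labels give no time for the unirradiated cells. Changes with time in culture therefore cannot be told apart here from a later response to radiation. DDIT4, an inhibitor of mTORC1, was 0.71 ± 0.25 higher at 3 h than at 1 h (adjusted p = 0.00147), with a second probe at -0.083 (adjusted p = 0.20). CDKN1A rose by a further 0.91 ± 0.69 (adjusted p = 0.0251), a call lost without 92-1, C32TG or Colo679, with an adjusted p of up to 0.0730. GADD45B was lower at 3 h than at 1 h (-0.46 ± 0.26, adjusted p = 0.00873), with a second probe at 0.0045 (adjusted p = 0.968). BUB1B fell by a further 0.48 (SD 0.25; adjusted p = 0.00758) and the checkpoint kinase TTK by 0.41 (SD 0.18; adjusted p = 0.00435). Of the p53 targets, 10 were higher at 3 h than at 1 h (18 when adjusted over the list alone; median 0.32, adjusted p = 5.91e-10, higher in 6 of 6 lines), and of the mitotic genes 11 were lower (22 when adjusted over the list alone; median -0.24, adjusted p = 1.17e-19, lower in 6 of 6 lines). These list tests gave adjusted p = 0.596 and adjusted p = 0.459 with an estimated correlation. The immediate early genes as a list did not pass (median -0.065, adjusted p = 0.636; limma called 0 of 16, also when adjusted over the list alone, with 7 at an unadjusted p under 0.05).

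The time comparison called 1445 probes, 804 higher and 641 lower at 3 h, for 427 named genes that rose and 273 that fell. Rises were 55.6% of calls with quantile normalization, 74.8% with median centring and 28.8% with the values as deposited. Each line counted: without HMV-II 694 calls were left, without Colo679 750, without 92-1 820, without MeWo 876, without C32TG 888 and without HMV-I 903, and without the arrays numbered 3 there were 797.

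The lines differed in how far p53 targets rose. At 3 h the median change of the list was 1.00 after carbon ions and 0.91 after X-rays in 92-1, 0.70 and 0.64 in C32TG, 0.45 and 0.36 in Colo679, and 0.55 and 0.45 in HMV-II. In HMV-I it was 0.087 and 0.12, and in MeWo 0.053 and 0.091. Within lines, only targets without a missing value in that line were tested, which left out CDKN1A in Colo679. After carbon ions 20 of 25 tested targets rose and 1 fell in 92-1, 21 of 26 rose in C32TG, 15 of 25 in Colo679, and 15 of 23 rose and 1 fell in HMV-II, against 4 of 26 that rose and 1 that fell in HMV-I, and 5 of 25 that rose and 3 that fell in MeWo. After X-rays 18 rose in 92-1, 21 in C32TG (1 fell), 14 in Colo679 (1 fell), 13 in HMV-II, 8 in HMV-I and 3 in MeWo. A permutation test of the difference in response between the 6 lines gave F = 49.2 with p = 0.0001, the smallest value 10000 permutations can give. This p covers only the spread between single arrays, which may share a culture. With 1 value per line and beam set, line against line by beam at 3 h gave F = 88.0 and an exact permutation p of 0.00139, the smallest that 720 orders of the lines can give (0.00463 after adjustment over 5 such tests). Without CDKN1A and GDF15, the 2 targets that came within 1 log2 of the highest spot on any array, these tests gave F = 33.0 (p = 0.0001) and F = 61.2 (exact permutation p = 0.00278).

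**Figure D1:**
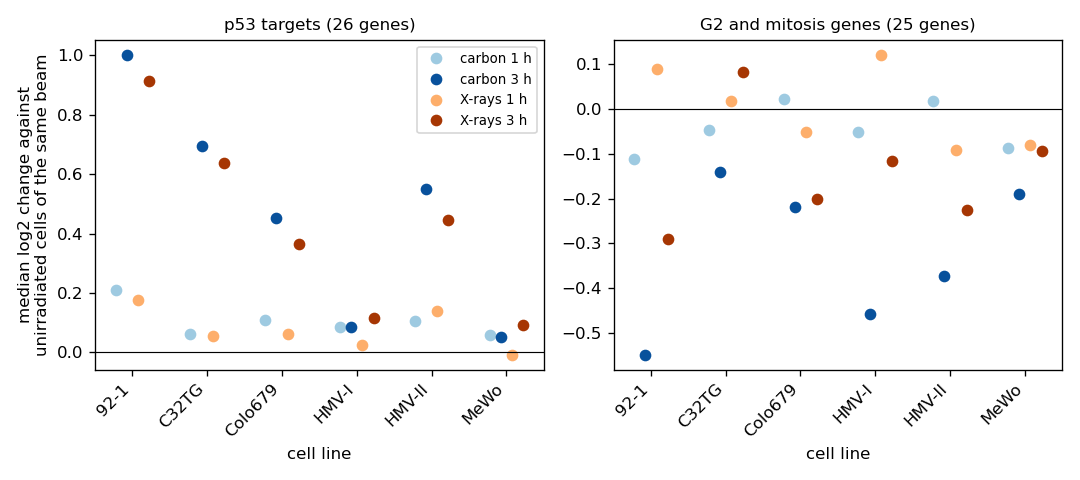
Median log2 change of the measured p53 targets (left) and of the measured genes of G2 phase and mitosis (right) against unirradiated cells of the same beam, for each line; points are medians over the genes of the list measured in that line, coloured by beam and time. At 3 h the p53 medians run from 0.053 in MeWo to 1.00 in 92-1 after carbon ions, and the mitotic medians after carbon ions lie below 0 in all 6 lines.

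CDKN1A, MDM2 and GDF15 were followed in every line, and each differed between lines. The brightest spots lay close together, with 30 to 101 spots of an array within 0.5 log2 of its highest, so that differences near this top are no exact measure of a response. CDKN1A rose at 3 h by 2.23 after carbon ions and 2.31 after X-rays in 92-1 (limma adjusted p = 1.31e-05 and 9.66e-06, n = 3 arrays per group), and by 1.91 and 1.78 in C32TG (4.72e-11 and 2.72e-10), with a pooled SD within groups of 0.34 and 0.13. In HMV-II it rose by 0.90 and 0.62 (limma adjusted p = 2.05e-05 and 0.00213), and in Colo679, where a missing value kept it out of the test, the measured differences were 1.20 and 1.55. At 3 h it stood 0.24 to 0.46 log2 below the highest spot in C32TG, 0.11 to 0.28 in Colo679 and 0.49 to 0.76 in HMV-II, so that these 3 lines have no exact order. It rose less in MeWo, by 0.61 and 0.37 (limma adjusted p = 1.57e-04 and 0.0347), and in HMV-I, by 0.34 and 0.45 (0.00576 and 6.00e-04). Unirradiated CDKN1A in HMV-I stood at intensities of 61.0 in the carbon-ion set and 140.8 in the X-ray set, a gap larger than either rise. MDM2, the ubiquitin ligase that limits p53, rose by 1.06 and 1.48 in C32TG (limma adjusted p = 6.55e-08 and 5.04e-10), by 0.86 and 0.93 in Colo679 (6.90e-07 and 3.63e-07), and by 0.78 and 0.74 in HMV-II (2.13e-04 and 0.00118). Its differences were 0.59 and 0.53 in 92-1, not tested because of a missing value, and 0.09 and 0.10 in HMV-I and -0.12 and 0.10 in MeWo (limma adjusted p = 0.486, 0.442, 0.572 and 0.735). Unirradiated MDM2 was dim, at intensities of 1.28 and 1.34 in 92-1 and 1.15 and 1.03 in MeWo, so its differences there are uncertain in size. C32TG and Colo679, where it rose, were dim as well, at 1.56 to 1.81. GDF15, a secreted stress cytokine, rose by 2.35 and 2.22 in 92-1 (limma adjusted p = 1.44e-11 and 7.13e-11) and by 1.80 and 1.38 in C32TG (1.79e-11 and 1.78e-09). At 3 h in C32TG it was 0.49 to 1.05 log2 below the highest spot. In Colo679 unirradiated GDF15 (intensities of 634 and 675 in the carbon-ion and X-ray sets) was already only 0.052 to 0.35 log2 below the highest spot, and in HMV-II 0.26 to 0.71, so that a rise like that in 92-1 could not have been measured in either line. The differences of 0.11 and 0.042 in Colo679 and 0.10 and 0.20 in HMV-II are therefore no estimate of the response. Away from the top, the differences were 0.071 and 0.11 in MeWo (limma adjusted p = 0.456 and 0.372) and 0.050 and 0.32 in HMV-I (0.715 and 0.0114). Unirradiated GDF15 also differed between the carbon-ion and X-ray sets, at intensities of 71.0 and 196.5 in HMV-I and 2.74 and 7.44 in 92-1.

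Across lines, MDM2 rose at 3 h by 0.54 ± 0.46 after carbon ions (adjusted p = 0.0259, higher in 5 of 6 lines) and by 0.65 ± 0.53 after X-rays (adjusted p = 0.0181, 6 of 6 lines). The carbon-ion call was lost without 92-1, C32TG, Colo679 or HMV-II (adjusted p up to 0.0792) and without the arrays numbered 1 (0.0541), and the X-ray call without HMV-II (0.0632). GDF15 did not pass across lines, with 0.75 ± 1.04 after carbon ions (adjusted p = 0.108) and 0.71 ± 0.89 after X-rays (adjusted p = 0.0845), higher in 6 of 6 lines for both, with Colo679 and HMV-II near the top of the scale. At 1 h MDM2 stood at 0.10 and 0.072 (adjusted p = 0.362 and 0.584) and GDF15 at -0.066 and -0.015 (adjusted p = 0.558 and 0.918) after carbon ions and X-rays. Within lines at 1 h, GDF15 fell in MeWo by 0.48 after carbon ions (limma adjusted p = 4.84e-05, n = 3 arrays per group), with -0.17 after X-rays (adjusted p = 0.328), and passed in no other line. CDKN1A rose at 1 h in HMV-I by 0.30 after carbon ions (limma adjusted p = 0.0275). The permutation tests of the difference between lines gave F = 18.1 for CDKN1A, 14.7 for MDM2 and 115.5 for GDF15, each with p = 0.0001 (0.000125 after adjustment over 5 such tests), the smallest value the permutations can give. These too cover only the spread between single arrays. With 1 value per line and beam set, the exact permutation tests gave F = 39.9, 28.2 and 67.7 with p = 0.00278, 0.00278 and 0.0278 (0.00463, 0.00463 and 0.0347 after adjustment). The values of GDF15 and CDKN1A near the top of the scale enter these tests. Over 92-1, HMV-I and MeWo, the 3 lines in which neither came within 1 log2 of the highest spot, the permutation tests over arrays gave F = 188.2 for GDF15 and 21.2 for CDKN1A, each with p = 0.0001.

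**Figure D2:**
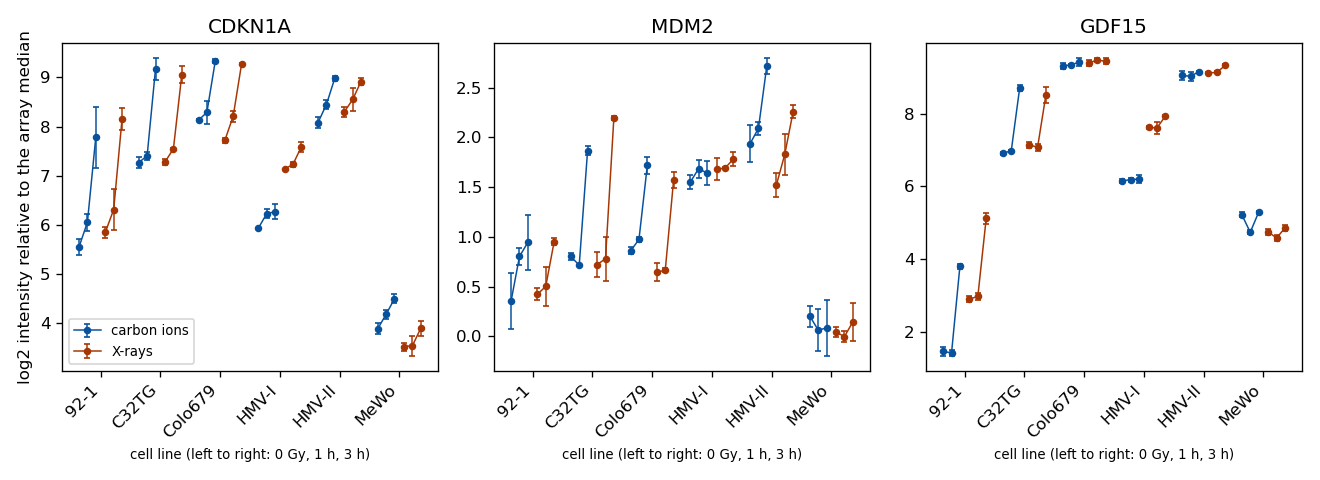
Log2 intensity of CDKN1A, MDM2 and GDF15 after quantile normalization, per line, for carbon ions and X-rays, from left to right unirradiated, 1 h and 3 h after 2 Gy. Points are means and bars the SD of 3 arrays, or of 2 for CDKN1A in unirradiated Colo679 of the carbon-ion set and for MDM2 in 92-1 at 3 h after X-rays. GDF15 rises at 3 h by 2.35 after carbon ions in 92-1. In Colo679 and HMV-II its unirradiated level in the deposited values already lies within 0.71 of the highest spot of the array, so that its response there is not measured.

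Within each line, the arrays were compared by limma's moderated F over the 4 contrasts. In 92-1, 3614 probes passed, with GDF15, CDKN1A and GADD45A as the largest rises at 3 h. In C32TG 5391 passed, and SESN1 rose by 2.05 after carbon ions and 1.70 after X-rays. In Colo679 6796 passed, with SESN2 up by 1.45 and 1.32. There CYCS, cytochrome c, was down with changes of -1.56 and -1.21, a call lost without the arrays numbered 2 (adjusted p = 0.0730). In HMV-I 6632 passed. Its largest rises included THBS1, the matrix protein thrombospondin, by 0.92 and 0.73, and RELB, an NF-kB subunit, by 0.67 and 0.93, and PIF1 changed by -1.30 and -1.43. In HMV-II 3019 passed, with ACER2 up by 1.03 and 1.20. NEAT1 changed there by -1.83 and -1.58, again lost without the arrays numbered 2 (adjusted p = 0.134). In MeWo 6409 passed. There NEAT1 fell by 2.02 after carbon ions (adjusted p = 2.92e-06), while its difference of -0.69 after X-rays did not pass (adjusted p = 0.0621). The autophagy protein GABARAP fell by 1.67 after carbon ions (adjusted p = 8.06e-06) with a difference of -0.41 after X-rays (adjusted p = 0.245).

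These counts within lines carry a limit, because the labels do not say whether the arrays of a group shared a culture. Set against each other within a line in limma, the unirradiated arrays of both beams differed as well. They gave 3731 called probes in 92-1, 12080 in C32TG, 5379 in Colo679, 14369 in HMV-I, 6465 in HMV-II and 21056 in MeWo. Only in Colo679 was this below the F count for irradiation. On simulated data, a spread of 0.1 log2 shared by the arrays of a group led the within-line F to call 7249 to 7805 of 31860 unchanged probes, more than were called in any line, whereas the test across lines called 21 for carbon ions and 20 for X-rays at 3 h. Without the arrays numbered 1, 2 or 3 in turn, the counts were 426, 429 and 1806 in 92-1, 2288, 2242 and 2484 in C32TG, 5377, 613 and 2716 in Colo679, 2138, 1934 and 3039 in HMV-I, 636, 161 and 1094 in HMV-II, and 2671, 1137 and 4722 in MeWo.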

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

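The tests of array brightness, of probes near the detection floor among all calls, of handling, response strength and unequal controls, the tests between lines with 1 value per line and beam set or without probes near the top of the scale, and the list tests on differences between beams and times, were chosen after the results were seen. The tests over other splits of the samples and over brightly measured p53 targets were set out before theirs. The permutation tests between lines of the mitotic list, CDKN1A, MDM2 and GDF15 were not among the planned tests.

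Many small changes shared by both beams were the first pattern weighed. After irradiation the brightest spot of the arrays was higher in 6 of 6 lines (by 0.19 ± 0.08 log2 at 3 h, exact sign-flip p = 0.03125), yet removing each probe's slope on it gave 3544 calls at 3 h after carbon ions, against 4300, with 2879 shared, which argues against brightness as the whole cause. As the source of most of these calls, probes near the detection floor are argued against as well, since 7.53% lay in the dimmest of 5 equal classes of kept probes. The filter on level had already left out the dimmest probes. Handling that differed between irradiated and unirradiated cultures stays open, because the changes of both beams correlated with r = 0.802 across probes outside the p53 and mitotic lists, which handling and a common response of the cells to radiation both predict, so that these cannot be told apart.

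The second pattern was the difference between lines in the rise of p53 targets (F = 49.2, p = 0.0001, the smallest the permutations can give), found by a test of the difference itself over single arrays, which may share a culture. With 1 value per line and beam set the exact permutation p was 0.00139, the smallest possible. The F was 50.6 after the brightness correction, which argues against brightness. It was 88.5 over the 16 of 26 targets whose unirradiated intensity was above 2 in every line and beam. This argues against dim target probes as the only cause. These 16 include CDKN1A and GDF15, which came near the top of the scale in some lines. The bright targets were not tested without them. The 24 targets left without these 2, dim ones included, gave F = 33.0 (permutation p = 0.0001). A weaker response in general was weighed for HMV-I and MeWo, where the list rose least. The mean rise of the list, divided by the SD of all probes' changes, differed 16.6-fold between lines, from 0.368 in MeWo to 6.10 in C32TG. That SD ran only from 0.13 in C32TG to 0.22 in Colo679, so the ratio mostly repeats the list mean and cannot decide. The SD itself was 0.17 in HMV-I and 0.19 in MeWo, against 0.18 in 92-1 and 0.13 in C32TG, where the list rose most. This argues against a weaker response over all probes in HMV-I and MeWo, as far as the SD measures it. The SD also holds the spread between arrays, so a smaller difference in general response stays open. No biological explanation was tested.

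The third pattern was the larger fall of mitotic genes after carbon ions at 3 h (median difference -0.22). It was -0.22 after the brightness correction too, which argues against brightness. Unequal unirradiated controls stay open: the irradiated arrays alone showed carbon ions above X-rays by 0.10 ± 0.30 on average (higher in 3 of 6 lines, exact sign-flip p = 0.469), while the controls differed by 0.31 ± 0.40 the same way. The difference between beams could therefore come from where the controls stood, or from a denser track of damage, and these cannot be told apart with separate controls per beam.

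CDKN1A differed between lines (F = 18.1, from 0.39 in HMV-I to 2.27 in 92-1 as the mean 3 h change), as did MDM2 (F = 14.7, from -0.01 in MeWo to 1.27 in C32TG) and GDF15 (F = 115.5, up to 2.28 in 92-1), each with a permutation p of 0.0001. GDF15 was near the top of the scale before irradiation in Colo679 and HMV-II, and CDKN1A near it at 3 h in C32TG, Colo679 and HMV-II. MDM2 was dim before irradiation in 92-1, C32TG, Colo679 and MeWo, at intensities of 1.03 to 1.81. Over 92-1, HMV-I and MeWo, away from the top, F was 188.2 for GDF15 and 21.2 for CDKN1A (permutation p = 0.0001). All of these cover only the spread between single arrays. With 1 value per line and beam set, over all 6 lines, the exact p was 0.00278 for CDKN1A, 0.00278 for MDM2 and 0.0278 for GDF15. The mitotic list differed between lines over single arrays (F = 3.34, permutation p = 0.0002), from -0.41 in 92-1 to -0.05 in C32TG, where the mean changes of the beams were -0.16 after carbon ions and 0.055 after X-rays. With 1 value per line and beam set it did not pass (F = 2.26, exact permutation p = 0.229).

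Between beams at 1 h, the list test put the change of immediate early genes from their own controls higher after carbon ions (median 0.13, adjusted p = 1.47e-04, higher in 6 of 6 lines; adjusted p = 0.50 with an estimated correlation). The list mean differed by 0.36 in HMV-I but by 0.0094 in 92-1 and 0.0073 in C32TG, and without HMV-I the median was 0.092 (adjusted p = 0.0440). In HMV-I the unirradiated carbon-ion controls stood at -0.26 against the X-ray controls. The change of interferon-stimulated genes was also higher (0.077, adjusted p = 0.0108, 6 of 6 lines; adjusted p = 0.424 with an estimated correlation), a call lost without 92-1 (0.043, adjusted p = 0.0889) and without the arrays numbered 1 or 2 (adjusted p = 0.0504 and 0.210). The p53 list differed by 0.032 (adjusted p = 0.0366, 5 of 6 lines; adjusted p = 0.459 with an estimated correlation), a call lost without the carbon-ion 1 h array 2 of MeWo (0.0674) or the unirradiated carbon-ion array 1 of Colo679 (0.0639), after the brightness correction (0.0622), without 92-1, C32TG, Colo679 or HMV-I (up to 0.0936) and without the arrays numbered 2 or 3 (up to 0.525). At 3 h the change of heat shock genes was lower after carbon ions (-0.12, adjusted p = 0.00148, 4 of 6 lines; adjusted p = 0.50 with an estimated correlation), a call lost with median centring (-0.065, adjusted p = 0.0682), with the values as deposited (-0.087, adjusted p = 0.118) and without the arrays numbered 3 (0.184); the median was -0.074 without 92-1 (adjusted p = 0.0107) and -0.069 without HMV-I (adjusted p = 0.044). The exact sign-flip test of the heat shock list mean at 3 h over lines gave p = 0.219. Its beam difference was -0.20 in 92-1, -0.25 in HMV-I and -0.31 in MeWo, and -0.016 to 0.026 in the other lines. Before irradiation, the heat shock mean of the carbon-ion controls stood at 1.20 in HMV-I and -1.02 in MeWo against the X-ray controls. Between times, 1445 probes differed, with p53 targets at 0.32 and mitotic genes at -0.24.

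Chance was weighed by other splits. Of the 32 sign patterns over the 6 lines, 1, the real one, gave as many calls at 1 h and 3 h after carbon ions (3430 and 4300, against at most 14 and 15 in another). The same held at 1 h and 3 h after X-rays (370 and 2292, against 0) and between times (1445, against 0). A share of 1 in 32 is the smallest these patterns can give. Flipping the sign of a line cancels a change shared by the lines, so few calls in other patterns were built in. The size of the gap to the other patterns therefore adds nothing against chance. Only the share of 1 in 32 bears on it, and chance is not excluded. For both comparisons of the beams and for their controls, the observed count was 0, which 32 of 32 patterns reach by construction, so the test says nothing about chance there. Within lines, 1 of 100 shuffles of the group labels within beam, the real one, gave as many calls in each line, with highest other counts of 174 in 92-1 (real 3614), 1190 in C32TG (5391), 873 in Colo679 (6796), 695 in HMV-I (6632), 174 in HMV-II (3019) and 1601 in MeWo (6409); such shuffles do not cover a culture shared by the arrays of a group.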

How the results depend on the processing

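The brightness correction, the values as deposited and the omission of single arrays or of targets near the top of the scale were chosen after the data were seen. The 4 calls of p53 targets and both calls of mitotic genes kept their direction and side of the threshold under median centring, no filter, the offset, each omitted replicate number, each omitted line, the brightness correction and the values as deposited, and lost the call with an estimated correlation, where the medians were 0.11, 0.49, 0.070 and 0.48 for p53 targets (carbon ions 1 h, 3 h, X-rays 1 h, 3 h) and -0.32 and -0.14 for mitotic genes at 3 h, with adjusted p = 0.419 to 0.424. The F of the p53 list between lines ran from 17.6 to 53.04 with a permutation p of 0.0001 throughout, and was 33.0 without the 2 targets near the top of the scale.

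Median centring gave 5235 calls at 1 h after carbon ions (3079 shared), 7089 at 3 h (3615 shared) and 3670 at 3 h after X-rays (2001 shared), and the cause was not tested. The ribosomal protein list, uncalled with quantile normalization, passed with the opposite sign at 1 h after X-rays with median centring (0.10) and as deposited (0.084), and at 3 h after carbon ions as deposited (0.14); the cause was not tested. X-rays at 1 h gave 239 calls without the level filter and 217 after the brightness correction, and HMV-II gave 1625 as deposited; the cause was not tested.

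The fit on all arrays called 8597 and 13957 probes after carbon ions, 3213 and 10029 after X-rays (1 h and 3 h), 292 and 368 between beams, 8725 between times and 17716 between controls, since it leaves out the spread between lines. With a replicate block these were 8859, 14039, 3518, 10235, 441, 504, 8936 and 14822. Replicate numbers did not pair the arrays in every set, but pairing in part is not excluded. Same-numbered arrays deviated together with a mean r of 0.0337 (lowest -0.402), against -0.0164 for other numbers. Of the same-numbered pairs, 30 exceeded 0.1, at most 6 of 9 in a set. In all, 53 arrays correlated best with their own number, and the count expected by chance was not computed. As a hint from the data, not the design, arrays did so in 8 of 9 cases in the carbon-ion set of Colo679. In that of MeWo it was 7 of 9. The mean r of same-numbered arrays reached 0.116 in the carbon-ion set of HMV-I and 0.110 in the X-ray set of HMV-II. In both sets of 92-1 and the X-ray set of C32TG it was lower than that of other numbers. Within lines the replicate block moved none of the 6 F counts by over 1.5 times. For HMV-II X-rays 1 h the calls went from 42 to 81 with it, and for HMV-II X-rays 3 h from 919 to 1723.

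With single lines, replicate numbers or arrays left out, calls ran from 1904 to 3658 (carbon ions 1 h), 1813 to 4947 (3 h), 113 to 370 (X-rays 1 h), 1159 to 2292 (3 h), 694 to 1444 (between times) and 0 to 1 (controls; the 1 without Colo679), and stayed at 0 between beams. Within lines they ran from 426 to 3614 in 92-1, 2242 to 5391 in C32TG, 613 to 6792 in Colo679, 1934 to 6632 in HMV-I, 161 to 3019 in HMV-II and 1137 to 7146 in MeWo. Fewer arrays and lines lower the power by construction. Leaving out either doubted array kept 23 of 23 leading results on their side of the threshold and within 1.5 times. Among the other 736 results, 662 stayed on their side with median centring, 17 lost and 51 gained a call; 34 lost a call with the brightness correction. The brightest probes have little room to rise, and the dimmest are measured least often, which limits what can be said of both.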

Other observations

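The brightness correction, the values as deposited and the omission of single arrays were tests chosen after the data were seen. The list tests themselves were planned, and none passed with an estimated correlation. Interferon-stimulated genes rose at 1 h after carbon ions, with 4 of 13 called (6 when adjusted over the list alone), a median of 0.13, an adjusted p of 4.55e-04 and adjusted p = 0.419 with an estimated correlation; the median was 0.077 without HMV-II (adjusted p = 0.00442) and 0.077 with the offset before log2 (adjusted p = 3.82e-04). IFIT3, an interferon-induced antiviral protein, rose by 0.37 ± 0.21 (adjusted p = 0.00516) in 6 of 6 lines. At 3 h after carbon ions (3 of 13 called, also when adjusted over the list alone; median 0.14, adjusted p = 0.0311) the call was lost with median centring (0.0620), as deposited (0.0554), with the brightness correction (0.0953), without HMV-I, HMV-II or the arrays numbered 1 (up to 0.119) and without the unirradiated carbon-ion array 1 of Colo679 (0.050). At 1 h after X-rays (2 of 13, 3 when adjusted over the list alone; 0.027, adjusted p = 0.0206) it was lost with the brightness correction (0.0630) and without HMV-II, MeWo or the arrays numbered 1 (up to 0.117), and the median was 0.015 without Colo679 (adjusted p = 0.0279). At 3 h after X-rays (0 of 13 in limma and when adjusted over the list alone, 4 at an unadjusted p under 0.05; 0.10, adjusted p = 0.0329) it was lost with each of 3 processing alternatives (0.0645 to 0.0758), without 92-1, HMV-I, HMV-II or MeWo (up to 0.0919) and without the arrays numbered 1 (0.188). These 3 had adjusted p = 0.419 with an estimated correlation.

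NF-kB targets were higher at 3 h after carbon ions (median 0.12, 4 of 12 rose, 5 when adjusted over the list alone, adjusted p = 0.0207) and X-rays (0.16, 0 of 12 rose in limma, 4 when adjusted over the list alone, 6 at an unadjusted p under 0.05, adjusted p = 0.0206), each in 6 of 6 lines and with adjusted p = 0.419 with an estimated correlation. The calls were lost without HMV-II (0.0788 and 0.0538), and the X-ray call also without HMV-I (0.0717) or the arrays numbered 2 (0.0555). RELB, an NF-kB subunit, rose by 0.45 ± 0.31 after carbon ions (adjusted p = 0.0159), a call lost without 92-1 or HMV-I (up to 0.0522). Heat shock genes were lower after carbon ions at 1 h (median -0.16, 3 of 10 fell, 4 when adjusted over the list alone, adjusted p = 0.0124) and 3 h (-0.19, 3 of 10, 7 when adjusted over the list alone, adjusted p = 0.00127), each in 6 of 6 lines and with adjusted p = 0.419 with an estimated correlation. Both calls were lost with median centring (0.158 and 0.139) and as deposited (0.230 and 0.228). HSPD1, the mitochondrial chaperonin, fell by 0.57 (SD 0.41; adjusted p = 0.0144) at 3 h in 5 of 6 lines. After X-rays at 1 h the heat shock median was -0.063 (adjusted p = 0.0311; adjusted p = 0.425 with an estimated correlation), a call lost with median centring (0.520), as deposited (0.639), with the brightness correction (0.0843), and without C32TG, Colo679, HMV-II, MeWo or the arrays numbered 1 (up to 0.133), and the median was -0.10 without 92-1 (adjusted p = 4.49e-04). At 1 h after carbon ions, histone genes passed (median 0.12, 1 of 8 rose, 6 when adjusted over the list alone, adjusted p = 0.0180; adjusted p = 0.419 with an estimated correlation), though not without the arrays numbered 3 (0.0866). Immediate early genes passed too (0.12, 2 of 16 rose, also when adjusted over the list alone, adjusted p = 0.0227, higher in 4 of 6 lines; adjusted p = 0.597 with an estimated correlation), though not without HMV-I (0.0952) or HMV-II (0.117). NRF2 targets passed at 1 h after X-rays (0.042, 0 of 10 in limma, 3 when adjusted over the list alone and 3 at an unadjusted p under 0.05, adjusted p = 0.0206; adjusted p = 0.419 with an estimated correlation), a call lost without 92-1 (0.0789), HMV-II (0.0618), C32TG (0.0522) or the arrays numbered 1 (0.194), with a median of 0.076 without the arrays numbered 3 (adjusted p = 0.00724).

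Other lists passed in no irradiation contrast. At 3 h after carbon ions and X-rays the medians were 0.017 and -0.023 for genes of the G1/S transition (adjusted p = 0.846 and 0.975), 0.028 and -0.0011 for DNA repair genes (0.545 and 0.975), 0.0010 and 0.026 for melanocyte genes (0.937 and 0.676), 0.076 and 0.076 for apoptosis genes (0.112 and 0.0889), and 0.087 and 0.090 for integrated stress response genes (0.371 and 0.300). Ribosomal proteins stood at -0.0081 and 0.0069, with signs and calls that moved with the scaling (0.14 and 0.12 as deposited, both past the threshold). Single members still passed. The apoptosis effector BAK1 rose by 0.32 ± 0.15 after carbon ions (adjusted p = 0.00751) and by 0.33 ± 0.14 after X-rays (adjusted p = 0.00725), and CHAC1, a glutathione-degrading enzyme, by 0.51 ± 0.32 after carbon ions (adjusted p = 0.00971), each in 6 of 6 lines. TYMS, the thymidylate synthase, rose by 0.24 ± 0.11 after carbon ions (adjusted p = 0.0161) and by 0.20 after X-rays (adjusted p = 0.0282), calls lost without 92-1, HMV-I or HMV-II for carbon ions (up to 0.0573), and without 92-1, HMV-II, MeWo or the arrays numbered 1 or 3 for X-rays (up to 0.0956). CCN1, a matricellular protein of the immediate early list, fell by 0.50 after X-rays (SD 0.30; adjusted p = 0.00725). Markers of fibroblasts (6 measured, -0.033 and 0.036), keratinocytes (2 measured, 0.18 and 0.059) and leukocytes (3 measured, 0.15 and 0.028) did not pass as lists.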
